A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 32 samples.

How the data were processed

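The study measured transcripts of the unicellular cyanobacterium Synechococcus elongatus by RNA sequencing. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with the KAPA mRNA HyperPrep kit and 7 PCR cycles. There were 4 genotypes (wild type, a pilB mutant, a sigF1 mutant and a sigF2 mutant, written WT, PilB, SigF1 and SigF2) and 2 time codes, D1 and D4, each with 4 replicates, which gives 8 groups and 32 libraries. The labels do not define the unit of D. Nothing in the labels says that the replicates came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

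The values are a normalized signal per feature that the authors deposited in 1 table for all libraries. Per the submitters' processing notes DESeq2 was used, with no version given. The aligner, the counting program, the use of strand in counting and the genome build are not given in the sources used here. The table held 2784 features: 2665 with a locus tag, 3 named EbfG and 116 predicted RNAs. It gave a gene symbol for 263 features and the product "hypothetical protein" for 1048. None of the locus tags matched the reference table of gene names (0 matches), so names, products and coordinates are those of the deposited table.

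The total of the values ranged from 9839609 to 27673019 per library. In every library 100% of the features had values that were whole multiples of 1 smallest step, within a tolerance of 0.05 of a step. Of the features, 37 to 119 lay at 1 to 20 steps. Counted in such steps, the libraries held 11680987 to 16568203. The values are not read counts as deposited and the steps were not taken as reads, so no count model was used and no counting interval is given. The number of replicates sets the precision.

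No 2 libraries held identical values (0 identical pairs), and the lowest chi-square per degree of freedom between replicates, on values in steps, was 73.2, far above sampling noise. Pearson correlations of log2 values between replicates, across features, ranged from 0.928 to 0.993.

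Values were analysed as log2(value + 1), so that a fold change of a low gene is understated. Features needed a value of at least 10 in at least 4 libraries, which removed 8 and left 2776. All 32 libraries entered 1 linear model with 8 group means and 24 residual degrees of freedom, fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend). Tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each mutant was compared with WT at the same time code, D4 with D1 within each genotype, SigF1 with SigF2 and PilB with SigF1 at each time code, and the mutant effect at D4 with that at D1 as an interaction. Means are of the deposited values, with the SD over 4 libraries. Fold changes come from the limma log2 differences. They are therefore not ratios of the printed means, and can lie far from them where the libraries of a group spread widely. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

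Gene lists, 34 in all, were fixed by locus tag, symbol or product words, and their wording was adapted to the annotation of the table before any comparison was made. A list of plasmid genes had 0 members, and the other 33 were tested with camera (preset correlation 0.01), with camera on an estimated correlation, and with fry. List p-values were adjusted over the 33 lists of 1 comparison. Members were also counted as adjusted over the list alone.

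The groups, the comparisons, the main test, the lists and the rule for named genes were set before the data were examined. Per comparison of a mutant with WT the rule names pilB, sigF1 and sigF2, every member of the biofilm region list, up to 10 genes in each direction with the largest change, and up to 4 called members of each list that passes camera. A gene of largest change had to be called, to have its 4 values of 1 group all on 1 side of the other 4, and to have a mean of at least 50 in the higher group. Other comparisons take up to 5 genes in each direction. Genes shared by PilB and SigF1 are ranked by the smaller of their changes. The text names fewer genes than the rule gives, and for comparisons of D4 with D1 and of mutants with each other it gives only part of the lists that camera called.

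Replicate numbers come from the labels. Same-numbered libraries were checked for deviating together from their group means, which counted as pairing where every correlation was over 0.1. This held for WT with PilB (0.60 to 0.91 at D1, 0.27 to 0.72 at D4), for SigF1 with SigF2 (0.16 to 0.73 at D1, 0.31 to 0.66 at D4) and for WT_D1 with WT_D4 (0.16 to 0.55). It did not hold for WT with SigF1 or SigF2, nor for PilB with SigF1. For the paired groups a fit on the 2 groups with the replicate number as a block is given where it changes the call of a gene or list named in the text.

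The test was checked on simulated data made from the means and spread of these libraries, with 200 of 2776 genes changed. Noise was drawn separately for each gene and library, so the simulation held no correlation between genes and no pairing of libraries. Its false calls therefore do not measure those in the real libraries. For PilB_D1 against WT_D1 it recovered 38.8% of genes changed 1.5-fold, 79.1% changed 2-fold and 92.4% changed 4-fold, with 9 false calls (6% of calls). For SigF2_D4 against WT_D4 the shares were 50.7%, 80.6% and 93.9%, with 7 false calls (4.5%). For the SigF2 interaction they were 25.4%, 61.2% and 90.9%, with 8 false calls (6.3%). For the lists, the nitrogen assimilation list changed 2-fold on 2775 genes for PilB_D1 against WT_D1 was called (adjusted p = 4.1e-53), and 0 of the other lists was. That check had no correlated genes either, so it does not show how often unchanged lists are called in the real libraries.

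Alternatives covered the pseudocount, the filter, the scaling (same total, quantile, and the total without stable and predicted RNAs), a replicate block, only the groups compared, each library left out in turn, and the list test. The rescaling without stable and predicted RNAs, the block on only the groups compared, leaving out the 4 D1 libraries numbered 4, and dropping stable and predicted RNAs from the counts were chosen after seeing the data. Comparisons that share the WT libraries were set beside 100 simulations of unchanged groups and beside the WT libraries divided between the comparisons. Other splits of the libraries were all 35 for 8 libraries, or 100 drawn. Features with an antisense partner, and near-identical copies, are uncertain, since counting by strand is not given.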

Results

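Biofilm-forming mutants of Synechococcus elongatus were compared with the wild type, which, per the design, asks which transcripts change with biofilm formation. Transcripts of 4 genotypes were measured at 2 time codes in 4 libraries per group. The PilB strain carries a transposon in pilB, the gene of the ATPase that extends type IV pili, and SigF1 carries an insertion in a gene of a SigF sigma factor, a subunit that directs RNA polymerase to its promoters. The SigF2 mutant, in another gene annotated as SigF, was included to set apart the genes of each factor. Totals of the normalized values were 9839609 to 27673019 per library. Along the principal components of the log2 values, the leading component held 48.9% of the variance and the next 15.6%.

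**Figure D1:**
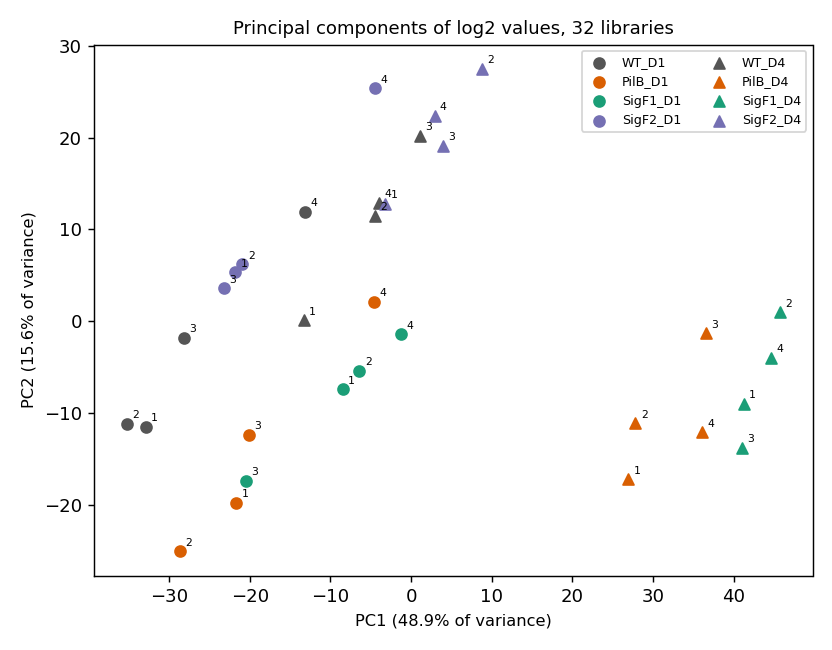
Each point is 1 library of the 32, placed by its scores on the leading 2 principal components of the log2 values, which hold 48.9% and 15.6% of the variance. Colours stand for the 4 genotypes and symbols for the time codes D1 and D4.

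Transcripts of stable RNA (rRNA, tRNA and the like) took 41.3% of the values in WT_D1, 43.1% in PilB_D1, 48.5% in SigF1_D1 and 40.0% in SigF2_D1. At D4 the mean shares were 51.5% in WT, 58.3% in PilB, 56.6% in SigF1 and 50.1% in SigF2. The RNA had been depleted of ribosomal RNA, so these shares also depend on the depletion. A rescaling to the same total includes these RNAs. Predicted RNAs took 1.88% in WT_D1 and 15.9% in SigF1_D4, with 6.92% in PilB_D4, 8.22% in SigF2_D4 and 2.79% in WT_D4. In SigF2_D4 most of that share was 1 feature, predRNA_1792487, so a share does not show a rise of predicted RNAs as a class. Same-numbered WT and PilB libraries deviated together, and so did SigF1 and SigF2 libraries, with mean correlations of 0.73 and 0.44 at D1, while WT libraries had 0.16 with SigF1 and 0.37 with SigF2, so the separation into 2 sets of libraries is not clear. If there were such sets, a difference between them could not be told apart from the genotypes in comparisons of SigF1 or SigF2 with WT or PilB.

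The mutated genes were read in every library. PilB libraries held less pilB transcript (Synpcc7942_2071, annotated as an ATPase, 2147525 to 2149559 on the minus strand, build not given in the sources used here). The mean was 1950 ± 301 (SD, n = 4) in PilB_D1 and 6860 ± 1120 in WT_D1, a 3.51-fold fall (limma adjusted p = 3.4e-11), and 1350 to 1590 (SD 98.5) in PilB_D4 and 7860 ± 1110 in WT_D4, a 5.25-fold fall (adjusted p = 3e-14). In the libraries labelled SigF1 pilB fell 1.66-fold at D1 and 2.44-fold at D4, and in SigF2_D4 it was 6190 ± 845 (adjusted p = 0.067, and 0.031 to 0.034 without WT_D4 replicate 1 or SigF2_D4 replicate 4). Transcript of sigF1 (Synpcc7942_1510, 1560399 to 1561178) fell 2.39-fold in SigF1_D1, from 517 ± 59.1 to 217 ± 36.4 (adjusted p = 2.9e-05). In SigF1_D4 it was 778 ± 164 against 607 ± 85.6 in WT_D4 (adjusted p = 0.13, and 0.043 without SigF1_D4 replicate 2). The sign of that D4 value turned to -0.68 (log2) with every library rescaled to the same total. Transcript of sigF2 (Synpcc7942_1784, 1852484 to 1853320) was not lower in SigF2: 8240 ± 7110 in SigF2_D1 against 3410 ± 3360 in WT_D1 (adjusted p = 0.11, and 0.021 without WT_D1 replicate 4), and 10000 ± 5380 in SigF2_D4 against 4970 ± 2640 in WT_D4 (adjusted p = 0.27). A whole-gene value does not show whether the product is intact, so it does not check the SigF2 labels, nor the SigF1 labels at D4. Those groups are therefore called the libraries labelled SigF1 and SigF2, and every direction given for them rests on the labels.

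PilB at D1. Of 15 pilus genes 6 fell. The small secreted EbfG proteins, which biofilm development requires, had more transcript, but their calls are lost without single libraries and in some other settings. With the replicate block these calls were not lost. The pilT gene (Synpcc7942_2070, the retraction ATPase) fell 23.5-fold, from 7610 ± 1120 in WT_D1 to 320 ± 5.8 in PilB_D1 (SD, n = 4), and pilC (Synpcc7942_2069, the inner membrane platform) fell 14.1-fold, to 598 ± 71 from 8440 ± 1300. The pilin gene Synpcc7942_0049, a PilA-like subunit of the filament, fell 15.5-fold, from 108000 ± 14400 to 7460 ± 3280. EbfG2 rose 4.51-fold, from 105 ± 66 to 451 ± 232, EbfG1 4.05-fold and EbfG3 3.49-fold. The genes pilB (Synpcc7942_2071), pilT, pilC and Synpcc7942_2068 lie side by side on the minus strand, from 2144446 to 2149559, and Synpcc7942_0048 lies beside Synpcc7942_0049.

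The type IV pilus list had 15 measured members, of which 6 fell and 0 rose (6 and 0 adjusted over the list alone), and 9 were not called. Its camera adjusted p was 1.6e-10, and adjusted p = 0.015 with an estimated correlation. The list holds pilB, the gene mutated in this strain, and pilT and pilC beside it. It was not tested without them, so its call cannot be read apart from the mutated locus. The members that fell were pilB, pilT, pilC, both PilA-like pilins and Synpcc7942_2349. The 2 pilins are close copies, and their values are uncertain where reads were shared. In the biofilm region list (EbfG1 to EbfG3 and Synpcc7942_1127 to Synpcc7942_1134, 11 members), 3 rose (6 adjusted over the list alone) and 0 fell, with an adjusted p of 0.097 for the list and 0.015 with the replicate block. With that block Synpcc7942_1128, Synpcc7942_1132, Synpcc7942_1133 and Synpcc7942_1134 were called too (adjusted p = 0.019, 0.017, 0.0018 and 0.0018), and so were the lists of phosphate uptake (0.0077, from 0.42), photosystem I (0.028, from 0.29) and phycobilisome genes (0.0077, from 0.097), all higher in PilB_D1. Without WT_D1 replicate 4 Synpcc7942_1133 was called as well (adjusted p = 0.037).

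Outside these lists, a group of adjoining genes fell together in PilB_D1: Synpcc7942_2483 by 8.38-fold (28000 ± 2780 to 3380 ± 674) and Synpcc7942_2482 by 6.03-fold, both hypothetical proteins. Synpcc7942_1890, also hypothetical, fell 12.3-fold (1920 ± 691 to 169 ± 93.2) and the methylase gene Synpcc7942_0046 fell 4.88-fold. The porin gene Synpcc7942_1607 rose 5.75-fold (761 ± 464 to 3910 ± 940, adjusted p = 0.0053), a glycosyltransferase, Synpcc7942_0986, 2.27-fold, and Synpcc7942_0905 5.78-fold. The predicted RNA antisense to pilB, predRNA_2148404, was listed at 0 in all WT_D1 libraries and at 60.9 ± 12 in PilB_D1, an uncertain value since counting by strand is not given.

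In all, 115 of 2776 genes were called in PilB_D1 against WT_D1, 55 higher and 60 lower, 49 of them by at least 2-fold. With the replicate block the count was 607 (360 higher, 247 lower), and without PilB_D1 replicate 2 it was 74. Rescaling to the same total gave 19 higher and 59 lower, and rescaling without stable and predicted RNAs 29 and 72. The EbfG calls are near the threshold (adjusted p = 0.037, 0.024 and 0.042 for EbfG1 to EbfG3). EbfG1 and EbfG3 were lost without WT_D1 replicate 1, 2 or 3 or PilB_D1 replicate 2, 3 or 4 (0.052 to 0.14 and 0.059 to 0.15), EbfG2 without WT_D1 replicate 1 or 2 or PilB_D1 replicate 3 or 4 (0.063 to 0.11), and all of them with the same total. With only the groups compared the EbfG calls were lost as well (0.16, 0.13 and 0.13), but not with the replicate block added. For each replicate number EbfG2 was higher in PilB_D1 (210, 312, 560 and 721) than in WT_D1 (43.7, 55.9, 140 and 180). The Synpcc7942_0905 call was lost without WT_D1 replicate 3 or PilB_D1 replicate 1 or 2 (0.051 to 0.087) and with only the groups compared (0.28), and its log2 change of 2.53 was 3.48 without PilB_D1 replicate 3. Transcript of sigF2 was not called in PilB_D1 (adjusted p = 0.54, and 0.017 with the replicate block).

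**Figure D2:**
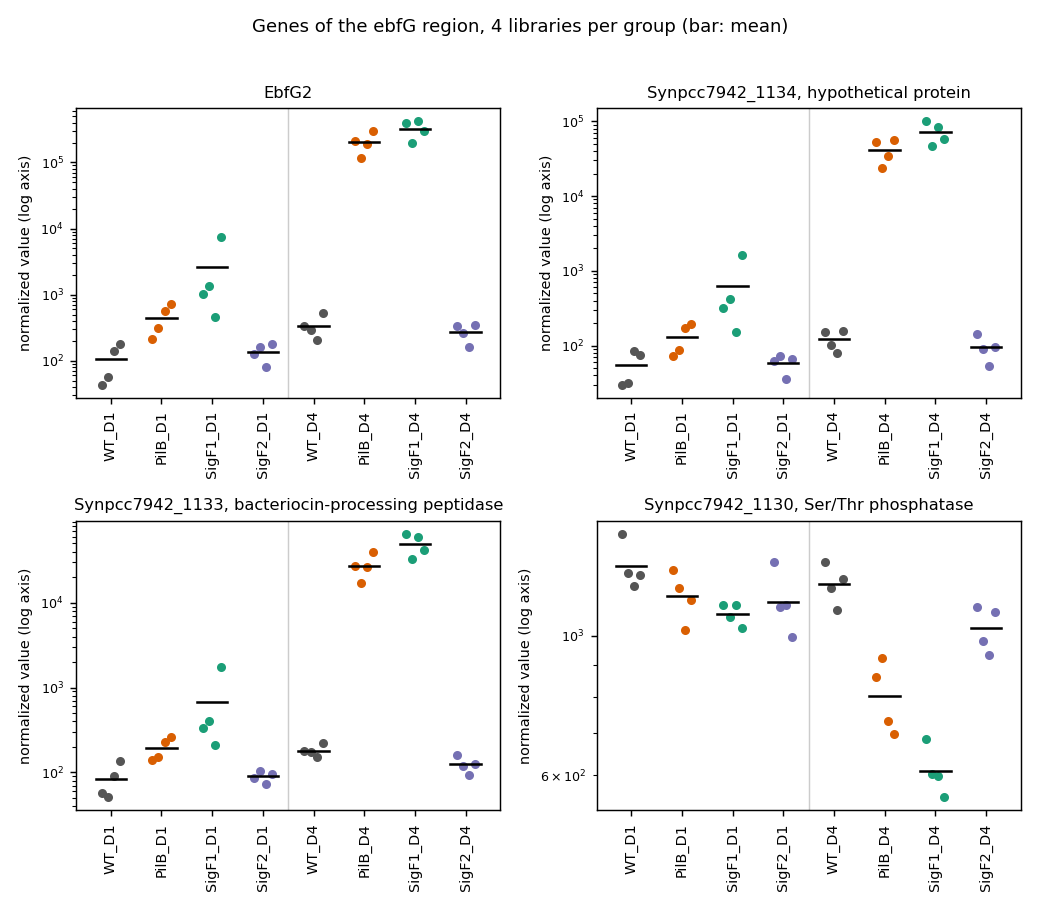
Normalized values (log axis) of EbfG2, Synpcc7942_1134, Synpcc7942_1133 and Synpcc7942_1130 in the 8 groups, with 1 point per library and a bar at the group mean. EbfG2 averaged 205000 in PilB_D4 and 325000 in SigF1_D4, and 339 or less in WT and in the libraries labelled SigF2.

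SigF1 at D1. In the libraries labelled SigF1, 6 of 11 biofilm region genes and 6 of 7 phosphate uptake genes rose, and 6 of 15 pilus genes fell. These list calls are lost with an estimated correlation (adjusted p = 0.44, 0.44 and 0.31). The pilin Synpcc7942_0049 fell 94.5-fold, from 108000 ± 14400 in WT_D1 to 1140 ± 175 in SigF1_D1 (SD, n = 4), and Synpcc7942_0048 fell 9.37-fold. EbfG2 rose 16.6-fold (105 ± 66 to 2600 ± 3310), EbfG1 15-fold and EbfG3 12.6-fold. Synpcc7942_1134 rose 8.41-fold and Synpcc7942_1133, a peptidase that lies beside it, 6.03-fold. These folds rest in part on SigF1_D1 replicate 4, with EbfG2 at 7540 against 454 to 1370 in the other 3 libraries. Without it the log2 changes were 3.15, 3.27 and 2.97 for EbfG1 to EbfG3 (from 3.91, 4.05 and 3.66), 2.42 for Synpcc7942_1134 (from 3.07), 1.97 for Synpcc7942_1133 (from 2.59) and 0.79 for Synpcc7942_1132 (from 1.41), all still called. The Synpcc7942_1132 call was lost with only the groups compared (0.13). The phosphate binding protein Synpcc7942_2445 rose 23.1-fold (496 ± 209 to 25800 ± 17300), a call lost with only the groups compared (0.07), and with a log2 change of 4.53 that was 3.93 without SigF1_D1 replicate 2 and 6.2 without SigF1_D1 replicate 4. The RNA-binding protein gene Synpcc7942_1999 fell 13.7-fold (169000 ± 72600 to 11400 ± 797).

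Of the 11 biofilm region genes, 6 rose and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00015, and adjusted p = 0.44 with an estimated correlation). Synpcc7942_1128 had an adjusted p of 0.056, and of 0.047 without SigF1_D1 replicate 2. Of the 15 pilus genes 6 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 2.5e-05, and adjusted p = 0.31 with an estimated correlation), with pilT at 5030 ± 708 against 7610 ± 1120. Of 7 phosphate uptake genes, 6 rose (7 adjusted over the list alone; adjusted p = 2.5e-05, and adjusted p = 0.44 with an estimated correlation), among them the transporter genes Synpcc7942_2441 to Synpcc7942_2443 by 3.89-fold to 4.15-fold, with Synpcc7942_2442 and Synpcc7942_2443 at log2 2.64 and 2.66 without SigF1_D1 replicate 4 (from 2.05 and 2.04). Nitrogen assimilation genes were lower as a list, with 4 of 20 lower and 0 higher (the same 4 and 0 adjusted over the list alone; adjusted p = 0.0043, and adjusted p = 0.82 with an estimated correlation). They included the ammonium transporter Synpcc7942_0442, at 61200 ± 4580 against 112000 ± 24000. In the polysaccharide and glycosyltransferase list 6 of 18 fell and 2 rose (6 and 2 adjusted over the list alone; adjusted p = 0.023, and adjusted p = 0.65 with an estimated correlation), with the cellulose synthase gene Synpcc7942_1398 5.9-fold lower. That list's call was lost without WT_D1 replicate 1 or SigF1_D1 replicate 2 (0.051 to 0.058).

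Photosystem II genes rose as a list, with 4 of 24 higher and 1 lower (12 and 1 adjusted over the list alone; adjusted p = 0.0043, and adjusted p = 0.65 with an estimated correlation). Of 15 photosystem I genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.024, and adjusted p = 0.8 with an estimated correlation), a list call lost without WT_D1 replicate 3 or SigF1_D1 replicate 1 or 2 (0.051 to 0.06) and with the same total. Of 16 phycobilisome genes 2 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.82 with an estimated correlation), lost without SigF1_D1 replicate 1 (0.051) and with quantile normalization (0.13). Of 53 ribosomal protein genes 5 fell and 3 rose (1 and 1 adjusted over the list alone; adjusted p = 0.019, and adjusted p = 0.99 with an estimated correlation), lost without WT_D1 replicate 2 or 3 or SigF1_D1 replicate 1 or 2 (0.061 to 0.18). Among photosystem genes Synpcc7942_0535 was at 32000 ± 1400 against 20900 ± 2320 (adjusted p = 0.00017, and 0.1 with the same total). The stable RNA share was 48.5% in these libraries and 41.3% in WT_D1.

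In total 564 genes were called in SigF1_D1 against WT_D1, 277 higher and 287 lower, 137 by at least 2-fold. Rescaling to the same total moved the median of all genes to -0.29 (log2) and gave 60 higher and 713 lower, so changes of that size are relative to the scaling.

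SigF2 at D1. In the libraries labelled SigF2, 14 of 24 photosystem II, 5 of 15 photosystem I and 9 of 16 phycobilisome genes rose, and 9 of 20 nitrogen assimilation and 13 of 34 tRNA synthetase and translation factor genes fell. The calls of these lists are lost with an estimated correlation (adjusted p = 0.58 for each), and the biofilm region list was not called. Synpcc7942_1999 fell 12.3-fold (169000 ± 72600 to 12800 ± 1200, SD, n = 4), and the adjoining genes Synpcc7942_0840 and Synpcc7942_0839 fell 6.08-fold and 4.82-fold. The heat shock protein gene Synpcc7942_2401 rose 8.73-fold (259 ± 69.5 to 4310 ± 4240), a call lost with only the groups compared (0.057). Its log2 change of 3.13 was 3.9, 2.49 and 2.54 without SigF2_D1 replicate 2, 3 and 4. The hypothetical protein Synpcc7942_1821 rose 4.97-fold. Of the 11 biofilm region genes 0 were called by limma, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.87), with EbfG2 at 138 ± 44.8 against 105 ± 66 (adjusted p = 0.53). Of the 15 pilus genes 0 were called, with 2 at an unadjusted p under 0.05 (list adjusted p = 0.73).

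Of 24 photosystem II genes 14 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 8.6e-06), of 15 photosystem I genes 5 rose and 0 fell (8 and 0; adjusted p = 0.0002), and of 16 phycobilisome genes 9 rose and 0 fell (11 and 0; adjusted p = 0.00014). The photosystem I subunit Synpcc7942_0535 rose 1.91-fold (20900 ± 2320 to 39900 ± 3490) and phycocyanin alpha (Synpcc7942_1053) 1.6-fold, the second call being lost with the same total. Of 20 nitrogen assimilation genes 9 fell and 0 rose (11 and 0; adjusted p = 0.0002), with nitrate reductase (Synpcc7942_1235) 2.19-fold lower. Of 34 tRNA synthetase and translation factor genes 13 fell and 1 rose (17 and 2; adjusted p = 0.0002), with glutamyl-tRNA synthetase (Synpcc7942_2393) 2.81-fold and lysyl-tRNA synthetase (Synpcc7942_2415) 2.75-fold lower. The phycobilisome list call was lost with quantile normalization too (0.056). The stable RNA list had 4 of 51 higher and 1 lower (0 and 0 adjusted over the list alone; adjusted p = 0.0052, and adjusted p = 0.88 with an estimated correlation), lost without WT_D1 replicate 3 (0.062). The mean stable RNA share was 40.0% against 41.3%, but WT_D1 replicate 1 held 51.81% and the other WT_D1 libraries 35.92% to 40.72%.

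The number called in SigF2_D1 was 608, 289 higher and 319 lower, 103 by at least 2-fold, and it was 385 without SigF2_D1 replicate 4. The split was 75 higher and 395 lower with the same total, and 105 and 529 with the total without stable and predicted RNAs, with medians of -0.17 and -0.16.

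PilB at D4. Transcripts of the EbfG proteins, Synpcc7942_1134 and Synpcc7942_1133 rose by 2 to 3 orders of magnitude. EbfG1 (1156700 to 1157019, minus strand) averaged 212000 ± 74000 in PilB_D4 and 417 ± 150 in WT_D4 (SD, n = 4), a 509-fold rise, and EbfG2 rose 604-fold and EbfG3 409-fold. The next genes on the same strand followed: Synpcc7942_1134 rose 330-fold, Synpcc7942_1133 (1153415 to 1155559) 146-fold to 27500 ± 9390, and Synpcc7942_1132 82.2-fold. Synpcc7942_1128 and Synpcc7942_1129, on the plus strand, rose 23.8-fold and 2.41-fold, whereas Synpcc7942_1130, a phosphatase, fell 1.51-fold. Of 15 pilus genes 9 fell, with pilT at 302 ± 17.4 against 8970 ± 1340 and Synpcc7942_0049 at 5780 ± 835 against 175000 ± 11600, falls of 29.4-fold and 30.5-fold.

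Of the 11 biofilm region genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 1.1e-08, and adjusted p = 0.082 with an estimated correlation). The remaining 2 were Synpcc7942_1127 (2960 ± 191 against 2610 ± 223, adjusted p = 0.17) and Synpcc7942_1131 (adjusted p = 0.067, 0.011 with the replicate block and 0.018 without WT_D4 replicate 3). Of the 15 pilus genes 9 fell and 1 rose (10 and 2 adjusted over the list alone; adjusted p = 2.3e-06, and adjusted p = 0.082 with an estimated correlation). Here too the list holds pilB, pilT and pilC and was not tested without them. Of 20 nitrogen assimilation genes 9 fell and 0 rose (11 and 0 adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.88 with an estimated correlation), with the ammonium transporter Synpcc7942_0442 at 29300 ± 1420 against 63800 ± 5110. With the replicate block the lists of ATP synthase (0.0039, from 0.19) and phycobilisome genes (0.017, from 0.08) were lower too, and the list of 2-component and cyclic nucleotide genes higher (0.031, from 0.19).

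Other genes with large falls were Synpcc7942_1890 (26.3-fold), Synpcc7942_2483 (16.7-fold, 33500 ± 1720 to 2040 ± 451) and the porin Synpcc7942_1607 (9.61-fold, 26700 ± 20300 to 2520 ± 1560), which was 5.75-fold higher in PilB_D1. Transcript of sigF1 rose 1.67-fold in PilB_D4 (1030 ± 260 against 607 ± 85.6, adjusted p = 0.0032, and 0.31 with the same total). Transcript of sigF2 was 13000 ± 5820 against 4970 ± 2640 (adjusted p = 0.067, 0.00059 with the replicate block and 0.045 without WT_D4 replicate 3). Stable RNA took 58.3% of the values in PilB_D4 and 51.5% in WT_D4, and predicted RNAs 6.92% and 2.79%.

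In PilB_D4 1085 genes were called, 564 higher and 521 lower, 257 by at least 2-fold. The split was 128 higher and 1359 lower with the same total (median -0.5), and 410 and 677 with the total without stable and predicted RNAs (median -0.11).

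**Figure D3:**
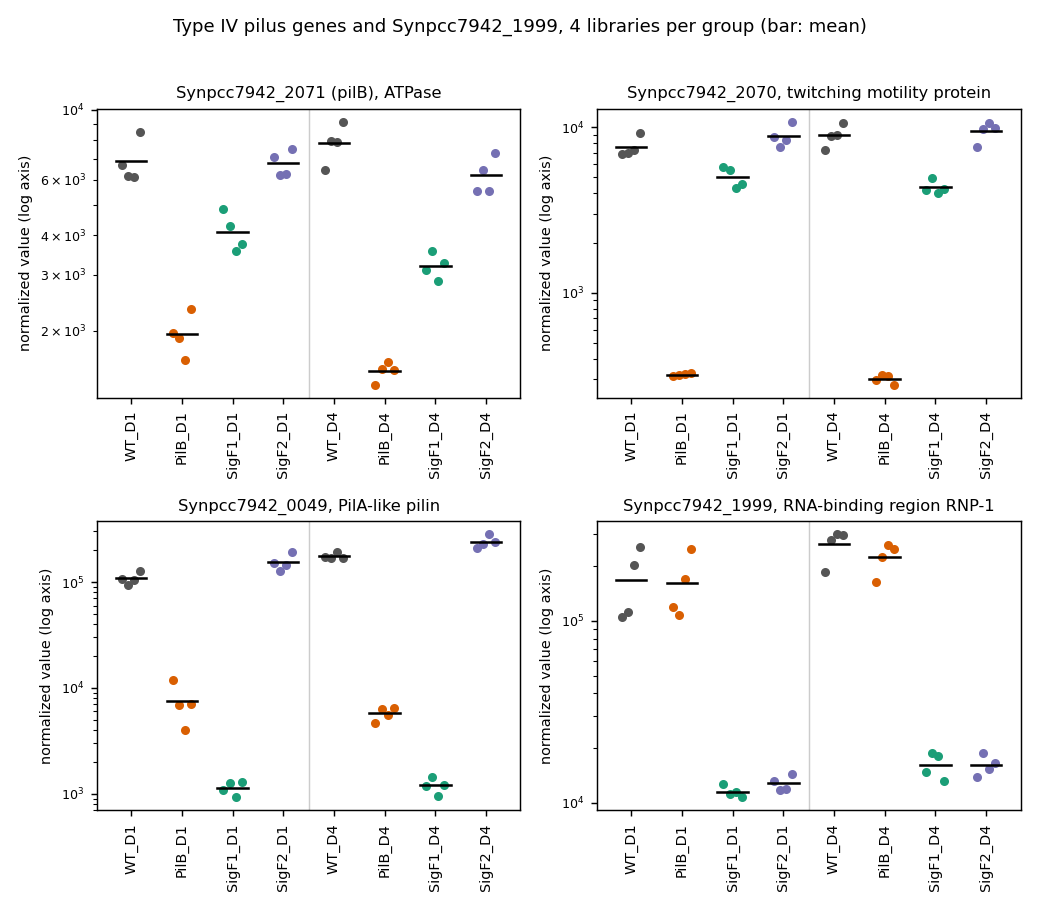
Normalized values (log axis) of pilB (Synpcc7942_2071), pilT (Synpcc7942_2070), the pilin Synpcc7942_0049 and Synpcc7942_1999 in the 8 groups, with 1 point per library and a bar at the group mean. Synpcc7942_0049 lay between 930 and 1450 in the libraries labelled SigF1 and between 93400 and 192000 in WT, and Synpcc7942_1999 between 10700 and 18800 in the libraries labelled SigF1 or SigF2.

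SigF1 at D4. The biofilm region rose further in the libraries labelled SigF1, and the pilins were far below WT. EbfG2 averaged 325000 ± 100000 against 339 ± 135 in WT_D4 (SD, n = 4), a 971-fold rise, and EbfG1 rose 795-fold, EbfG3 698-fold, Synpcc7942_1134 579-fold, Synpcc7942_1133 267-fold and Synpcc7942_1132 147-fold. Synpcc7942_1128 rose 30.8-fold and Synpcc7942_1129 3.18-fold, and Synpcc7942_1130 fell 1.97-fold. The pilin Synpcc7942_0049 fell 147-fold (175000 ± 11600 to 1200 ± 203) and Synpcc7942_0048 11.6-fold, while pilT and pilB fell 2.06-fold and 2.44-fold. The porin Synpcc7942_1607 fell 52.3-fold, imelysin (Synpcc7942_1462) 21.7-fold and Synpcc7942_1999 16.3-fold.

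Of the 11 biofilm region genes 10 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 2.1e-06, and adjusted p = 0.28 with an estimated correlation). Rises of Synpcc7942_1127 and Synpcc7942_1131 were small (log2 0.31 and 0.95) and turned to -0.72 and -0.07 with the same total; the former was also lost without WT_D4 replicate 2 or SigF1_D4 replicate 3 (0.055 to 0.064) and with only the groups compared (0.059). Of the 15 pilus genes 12 fell and 0 rose (12 and 1 adjusted over the list alone; adjusted p = 0.00019, and adjusted p = 0.28 with an estimated correlation). Of 20 nitrogen assimilation genes 14 fell and 1 rose (14 and 2 adjusted over the list alone; adjusted p = 0.022, and adjusted p = 0.97 with an estimated correlation), a list call lost without SigF1_D4 replicate 1 (0.081). The ammonium transporter Synpcc7942_0442 fell 3.23-fold to 20100 ± 4910, and the nitrate transport genes Synpcc7942_1237 to Synpcc7942_1239 were at 0.415 to 0.455 of WT. Transcript of sigF2 rose 4.58-fold (20600 ± 6120 against 4970 ± 2640, adjusted p = 0.0049, and 0.098 with the same total).

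In SigF1_D4 1541 genes were called, 742 higher and 799 lower, 529 by at least 2-fold, while predicted RNAs took 15.9% of the values and stable RNA 56.6%. The split was 96 higher and 2040 lower with the same total (median -1.03), and 439 and 1186 with the total without stable and predicted RNAs (median -0.29).

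SigF2 at D4. In the libraries labelled SigF2, 8 of 24 photosystem II, 6 of 15 photosystem I and 10 of 16 phycobilisome genes rose, and the biofilm region list was not called. The calls of these 3 lists are lost with an estimated correlation (adjusted p = 0.71 for each) and with quantile normalization. Synpcc7942_1999 fell 16.3-fold (265000 ± 53000 to 16100 ± 2050, SD, n = 4), Synpcc7942_0100 5.84-fold, Synpcc7942_0840 5.41-fold, the porin Synpcc7942_1607 4.14-fold and dprA (Synpcc7942_0703), whose product handles incoming DNA in transformation, 3.48-fold. The heat shock gene Synpcc7942_2401 rose 14.3-fold (785 ± 195 to 23600 ± 34900), with a log2 change of 3.84 that was 2.91 without SigF2_D4 replicate 3, and the predicted RNA predRNA_1792487 7-fold (140000 ± 54800 to 1050000 ± 513000). EbfG1, EbfG2 and EbfG3 were at 316 ± 71.6, 276 ± 85.8 and 163 ± 66.1 against 417 ± 150, 339 ± 135 and 241 ± 99.5 (adjusted p = 0.72, 0.78 and 0.5).

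By limma 0 of the 11 biofilm region genes were called, with 1 at an unadjusted p under 0.05 (list adjusted p = 0.43), and 1 of the 15 pilus genes fell (list adjusted p = 0.41). Of 24 photosystem II genes 8 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 0.00095), of 15 photosystem I genes 6 rose and 0 fell (6 and 1; adjusted p = 0.0087) and of 16 phycobilisome genes 10 rose and 0 fell (11 and 0; adjusted p = 0.00032). With quantile normalization none of these lists was called (0.17 for photosystem II, 0.2 for photosystem I and 0.096 for phycobilisome genes). The photosystem II protein Synpcc7942_1705 rose 2.2-fold, Synpcc7942_1322 of photosystem I 1.84-fold and the phycocyanin beta genes Synpcc7942_1047 and Synpcc7942_1052, near-identical copies, 1.63-fold each. Calls of that pair were lost without SigF2_D4 replicate 3 (0.064 and 0.059), with the same total and with only the groups compared (0.1 and 0.097).

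The 537 genes called in SigF2_D4 were 284 higher and 253 lower, 76 of them by at least 2-fold. With the same total the split was 49 and 602 (median -0.28), and with the total without stable and predicted RNAs 127 and 449 (median -0.14).

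**Figure D4:**
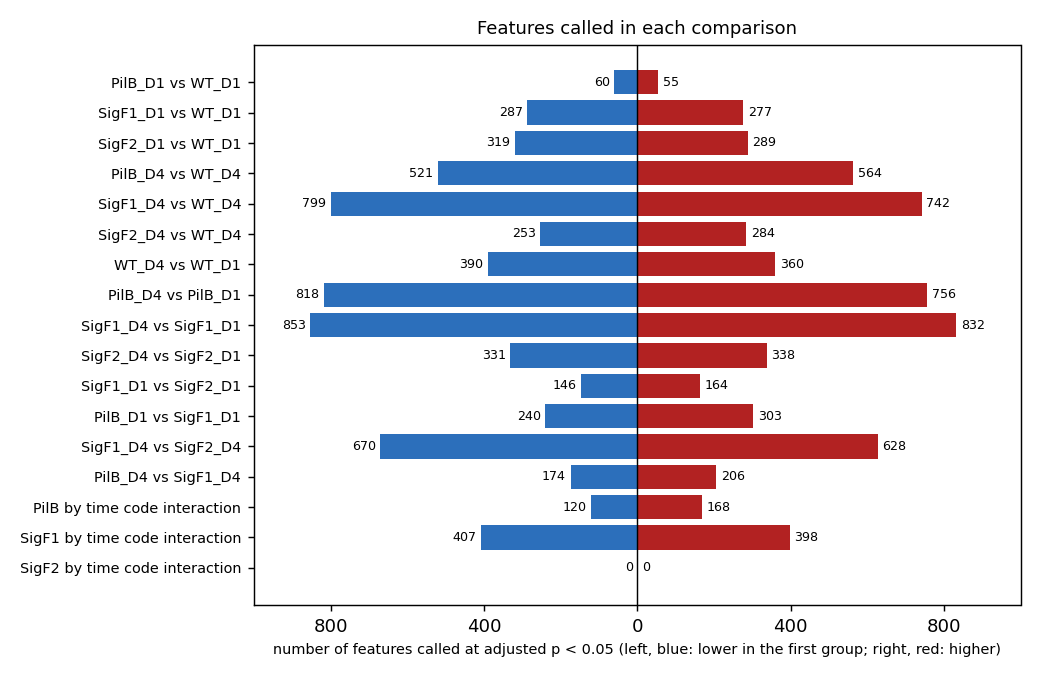
Number of genes called higher and lower in each comparison (limma adjusted p under 0.05, 2776 genes tested). The comparisons of mutants with WT range from 115 genes in PilB_D1 to 1541 in SigF1_D4.

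The biofilm-forming strains shared many calls. At D4, 966 genes were called in the same direction in PilB and in the libraries labelled SigF1, 495 higher and 471 lower, and 1 in opposite directions. The EbfG genes, Synpcc7942_1132, Synpcc7942_1133 and Synpcc7942_1134 led the shared rises, and Synpcc7942_0049, Synpcc7942_1890 and Synpcc7942_2483 were among the shared falls. At D1, 64 genes were shared, 23 higher and 41 lower, with 3 opposite. Independent lists of these sizes would share 301 genes at D4 and 11.7 at D1. Unchanged groups simulated against the same WT libraries shared a median of 0, with a highest value of 0 at D4 and 2 at D1. The simulated groups held no changed genes, so few calls could be shared. These simulated counts therefore do not measure what the shared WT libraries add to the overlap of changed genes. With the WT libraries divided between the comparisons the overlap was 610 to 743 genes at D4 and 32 to 39 at D1. Across genes, which are not independent replicates, the covariance of the fold changes was 0.86 at D4 against a simulated 0.03, and 0.79 to 0.84 with the WT libraries divided. At D1 it was 0.14 against 0.04, and 0.01 to 0.13 with the WT libraries divided. The simulations share all WT libraries and leave out the pairing of WT with PilB libraries, so they are no measure for the divided values. The correlation was 0.91 at D4 (simulated median 0.49, range -0.64 to 0.93, divided 0.79 to 0.88) and 0.52 at D1 (simulated median 0.53, divided 0.02 to 0.48).

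The libraries labelled SigF1 and SigF2 were compared directly. At D4 EbfG2 was 1180-fold higher in SigF1 (325000 ± 100000 against 276 ± 85.8, SD, n = 4), and the pilin Synpcc7942_0049 was 200-fold lower (1200 ± 203 against 239000 ± 31100). At D1 EbfG1 was 10.9-fold higher, Synpcc7942_0049 134-fold lower, Synpcc7942_0499 9.9-fold higher and Synpcc7942_1821 20-fold lower. Without SigF1_D1 replicate 4 the log2 difference of EbfG1 at D1 was 2.69 (from 3.45). The biofilm region had 6 of 11 genes higher and 0 lower at D1 (6 and 0 adjusted over the list alone; adjusted p = 6.9e-06, and adjusted p = 0.21 with an estimated correlation) and 9 higher and 1 lower at D4 (9 and 1; adjusted p = 6.5e-09, and adjusted p = 0.11 with an estimated correlation). Pilus genes were lower, 7 of 15 at D1 (7 and 1 higher adjusted over the list alone; adjusted p = 4.6e-07, and adjusted p = 0.11 with an estimated correlation) and 9 with 1 higher at D4 (10 and 1; adjusted p = 0.00018, and adjusted p = 0.3 with an estimated correlation). At D1 the phosphate uptake list was higher in SigF1 (6 of 7, and 7 adjusted over the list alone; adjusted p = 2e-07, and adjusted p = 0.21 with an estimated correlation). At D4 the phycobilisome list was lower (13 of 16 lower and 1 higher, the same adjusted over the list alone; adjusted p = 7.6e-05, and adjusted p = 0.87 with an estimated correlation). Synpcc7942_1132 was 2.76-fold higher at D1 (adjusted p = 0.0089, 0.069 with the replicate block and 0.14 with only the groups compared), with a log2 difference of 0.84 without SigF1_D1 replicate 4 (from 1.46). With the block Synpcc7942_1131 at D1 (0.033, from 0.34) and sigF2 (Synpcc7942_1784) at D4 (0.0013, from 0.15) were called higher in SigF1. With the block the D1 lists of photosystem I (0.029, from 0.13), phycobilisome (0.013, from 0.22) and stable RNA genes (0.0062, from 0.33) were called lower, as were ATP synthase (0.0034, from 0.13) and nitrogen assimilation genes (0.035, from 0.13) at D4.

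At D1 310 genes differed between them, 164 higher and 146 lower in SigF1, 540 with the replicate block and 202 without SigF2_D1 replicate 3 or 4. At D4 1298 differed, 628 higher and 670 lower. Rescaled to the same total the splits were 69 and 165 at D1 and 94 and 1805 at D4, and without stable and predicted RNAs in the total 281 and 85 and 422 and 868.

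PilB was compared with the libraries labelled SigF1. Genes beside pilB were lower in PilB, with pilT 15.5-fold lower in PilB at D1 (320 ± 5.8 against 5030 ± 708, SD, n = 4) and 14.3-fold lower at D4, and pilC 10-fold and 7.22-fold lower. Synpcc7942_1999 was 13.3-fold higher in PilB at D1 and 13.8-fold higher at D4, and the pilin Synpcc7942_0049 was 4.82-fold higher at D4. At D1 EbfG1, EbfG2 and EbfG3 were lower in PilB (log2 -1.89, -1.88 and -1.86, adjusted p = 0.019, 0.021 and 0.012), calls lost without PilB_D1 replicate 1 or SigF1_D1 replicate 4 and, for EbfG1 and EbfG2, without PilB_D1 replicate 2 (0.061 to 0.12), and all lost with only the groups compared (0.16, 0.17 and 0.13). Without SigF1_D1 replicate 4 the log2 values were -1.13, -1.10 and -1.16. At D4 they were not called, with EbfG2 at 205000 ± 74200 against 325000 ± 100000 (adjusted p = 0.46). The biofilm region list was lower in PilB at D1 (5 of 11 lower and 0 higher, 7 and 0 adjusted over the list alone; adjusted p = 0.0084, and adjusted p = 0.91 with an estimated correlation), a call lost without SigF1_D1 replicate 4 (0.11). The polysaccharide and glycosyltransferase list was higher, 8 of 18 at D1 (8 adjusted over the list alone; adjusted p = 0.00047, and adjusted p = 0.67 with an estimated correlation). At D1 543 genes differed, 303 higher and 240 lower in PilB, with 352 without PilB_D1 replicate 1 and 339 without PilB_D1 replicate 2. At D4 380 differed, 206 higher and 174 lower, with 212 without PilB_D4 replicate 2. With the same total the splits were 391 and 63 at D1 and 1482 and 13 at D4, and 486 and 56 at D4 with the total without stable and predicted RNAs.

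Between D1 and D4 in the wild type, 7 of 7 phosphate uptake genes rose and 37 of 53 ribosomal protein genes fell, list calls lost with an estimated correlation (adjusted p = 0.42 for each). The phosphate binding protein Synpcc7942_2445 rose 141-fold (496 ± 209 to 67900 ± 19100, SD, n = 4), the regulator Synpcc7942_2356 of the Crp/Fnr family 41.4-fold, imelysin (Synpcc7942_1462) 31.9-fold and the porin Synpcc7942_1607 31.1-fold. The cyclic nucleotide-binding protein gene Synpcc7942_1254 fell 7.62-fold and Synpcc7942_2043, a decarboxylase of polyamine synthesis, 6.99-fold. Of 7 phosphate uptake genes 7 rose (7 adjusted over the list alone; adjusted p = 1.6e-07, and adjusted p = 0.42 with an estimated correlation), and of 53 ribosomal protein genes 37 fell and 0 rose (41 and 1 adjusted over the list alone; adjusted p = 6.2e-14, and adjusted p = 0.42 with an estimated correlation). EbfG1, EbfG2 and EbfG3 rose 3.84-fold, 3.58-fold and 3.15-fold (adjusted p = 0.013, 0.019 and 0.019). These EbfG calls were lost without WT_D1 replicate 1 (0.059 to 0.074 over the libraries that end them) and, for EbfG2 and EbfG3, without WT_D1 replicate 2 or WT_D4 replicate 4. With the replicate block the biofilm region (0.017, from 0.056) and chaperone and protease lists (0.028, from 0.075) were called higher, as was Synpcc7942_1129 (0.043), and Synpcc7942_1131 was lower (0.045). In WT, 750 genes were called between the time codes, 360 higher and 390 lower at D4. In the libraries labelled SigF2 Synpcc7942_2445 rose 155-fold, and 669 genes were called, 338 higher and 331 lower, with 443 without SigF2_D1 replicate 2. The splits with the same total were 129 and 713 in WT and 81 and 922 in SigF2, and 369 and 214 in SigF2 with the total without stable and predicted RNAs.

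In PilB EbfG1 rose 483-fold from D1 to D4 (473 ± 258 to 212000 ± 74000, SD, n = 4), and in the libraries labelled SigF1 EbfG2 rose 210-fold (2600 ± 3310 to 325000 ± 100000), with a log2 change of 7.71 that was 8.49 without SigF1_D1 replicate 4. Of the 11 biofilm region genes 9 rose and 1 fell in PilB (9 and 1 adjusted over the list alone; adjusted p = 1.4e-06, and adjusted p = 0.38 with an estimated correlation), and 8 rose and 1 fell in SigF1 (8 and 1; adjusted p = 6.3e-05, and adjusted p = 0.53 with an estimated correlation). The phycobilisome list was lower at D4 in all 4 genotypes. In PilB and SigF1 14 of 16 genes fell in each, with 1 higher (14 and 1 adjusted over the list alone in each; adjusted p = 2.1e-05 and 6.3e-05, and adjusted p = 0.48 and 0.66 with an estimated correlation). In WT 7 fell and 1 rose (7 and 1; adjusted p = 0.0041, and adjusted p = 0.62 with an estimated correlation), and in SigF2 6 fell and 0 rose (7 and 1; adjusted p = 0.0019, and adjusted p = 0.72 with an estimated correlation). Genes called were 1574 in PilB (756 higher, 818 lower) and 1685 in SigF1 (832 higher, 853 lower). With the same total the splits were 220 and 1556 in PilB and 163 and 1901 in SigF1, and 598 and 1059 in SigF1 with the total without stable and predicted RNAs.

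Tests of the interaction asked whether a mutant's difference from WT itself differed between D4 and D1. For PilB 288 genes were called, 168 higher and 120 lower, and the biofilm region list had 8 of 11 higher and 0 lower (8 and 1 adjusted over the list alone; adjusted p = 1.5e-13, and adjusted p = 0.017 with an estimated correlation). The phycobilisome list was lower (2 of 16, and 10 adjusted over the list alone; adjusted p = 0.00013, and adjusted p = 0.77 with an estimated correlation), and so was that of nitrogen assimilation (4 of 20, and 11 adjusted over the list alone; adjusted p = 0.00059, and adjusted p = 0.77 with an estimated correlation). The lists of pilus (adjusted p = 0.047), photosystem I (0.047), photosystem II (0.047) and ATP synthase genes (0.043) were lower too, calls lost when any of 10, 8, 9 and 6 single libraries was left out (0.055 to 0.15) and with an estimated correlation (adjusted p = 0.77, 0.77, 0.83 and 0.83). The photosystem II call was also lost with the replicate block, both over all 32 libraries and on only the groups compared. The count was 451 with the replicate block, 175 without WT_D4 replicate 4 and 180 without PilB_D1 replicate 2. For SigF1 805 genes were called, 398 higher and 407 lower, and the biofilm region list had 8 higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 1e-06, and adjusted p = 0.3 with an estimated correlation). The phycobilisome list was lower there too (7 of 16, and 10 adjusted over the list alone; adjusted p = 0.0012, and adjusted p = 0.82 with an estimated correlation). For SigF2 limma called 0 genes, with 78 at an unadjusted p under 0.05. Camera called 4 lists for SigF2, although 0 of their genes were called: tRNA synthetase and translation factor genes passed camera as higher (adjusted p = 2.4e-06, and adjusted p = 0.85 with an estimated correlation), and so did nitrogen assimilation genes (adjusted p = 0.0042, and adjusted p = 0.95 with an estimated correlation). The latter call was lost without WT_D1 replicate 2, WT_D4 replicate 3 or SigF2_D1 replicate 4 (0.086 to 0.094). Pilus genes (adjusted p = 0.018, and adjusted p = 0.85 with an estimated correlation) and iron genes (adjusted p = 0.0056, and adjusted p = 0.85 with an estimated correlation) passed as lower. The pilus call was lost when any of 5 single libraries was left out (0.053 to 0.13), and the iron call with any of 3 (0.065 to 0.12). The porin Synpcc7942_1607 had the lowest PilB interaction (log2 -5.79, SE 0.78), and imelysin (Synpcc7942_1462) the lowest for SigF1 (log2 -5.44, SE 0.78). Without SigF1_D1 replicate 4 the SigF1 values of Synpcc7942_2445 and Synpcc7942_2356 were -6.64 and -6.33 (from -4.97 and -5.07), so the rank of imelysin depends on that library. With the same total the splits were 30 and 415 for PilB and 63 and 1347 for SigF1, and 199 and 662 for SigF1 with the total without stable and predicted RNAs.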

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

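The tests of the WT libraries as a shared baseline and of a shared batch, the rescaling without stable and predicted RNAs that tests the normalization, all tests of the sigF2 value and all tests of the D1 libraries numbered 4 were chosen only after the result was seen; the splits of the libraries were planned before.

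The biofilm region stood out because its differences from WT grew from D1 to D4. For PilB the difference of differences (log2, limma interaction) was 6.97 for EbfG1, 7.07 for EbfG2, 6.87 for EbfG3, 7.11 for Synpcc7942_1134, 5.92 for Synpcc7942_1133, 5.8 for Synpcc7942_1132, 3.62 for Synpcc7942_1128 and 1.48 for Synpcc7942_1129. For SigF1 these values were 5.73, 5.87, 5.79, 6.1, 5.47, 5.78, 3.85 and 1.6, and Synpcc7942_1130 had -0.73. Without SigF1_D1 replicate 4 the first 6 of the SigF1 values were 6.49, 6.65, 6.48, 6.75, 6.09 and 6.41. The Synpcc7942_1129 interactions did not pass with every library rescaled to the same total (adjusted p = 0.053 and 0.065). Transcript of sigF1 had an interaction of 1.6 in SigF1. Transcript of pilB had -0.58 in PilB and -0.55 in SigF1, calls lost when any of 13 and 5 single libraries was left out (adjusted p = 0.051 to 0.11 and 0.054 to 0.069), the PilB call also with only the groups compared (0.083). In all 288 genes for PilB and 805 for SigF1 passed this test.

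A single library lay far from the other 3 of its group in 5 of 144 groups and measures tested with Dixon's ratio, by passing its 5% critical value, where chance gives about 1 in 20, or 7.2. Transcript of sigF1 in WT_D4 replicate 1 had a ratio of 0.918. In WT_D1 replicate 1 the total of values had 0.835 and the rRNA share, 45.8%, had 0.888. The predicted RNA share had 0.945 in SigF2_D1 replicate 4, at 7.52%, and 0.856 in SigF2_D4 replicate 1, at 5.03%.

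At D1, 266 genes were called in the same direction in SigF1 and SigF2 against WT (131 higher, 135 lower, 8 opposite), where independent lists would share 61.8, and 42 were at least 2-fold in both. Sharing of the WT libraries as the whole cause is argued against, since 94 or more genes were shared with the WT libraries divided between the comparisons, at least 3.62 times what independent lists would share. With PilB as the baseline for SigF1 alone, and WT still that for SigF2, 206 genes were shared (59.8 if independent), but same-numbered WT and PilB libraries deviate together (mean correlation 0.73), so these baselines are not independent. Rescaling without stable and predicted RNAs kept 69.5% of the genes, 185 of 266, which argues against the normalization as the whole cause. A culture or library batch shared by SigF1 and SigF2 may contribute: same-numbered libraries correlated at 0.44, WT with SigF1 at 0.16 and WT with SigF2 at 0.37, which is not far below. It cannot be told apart from an effect common to loss of either SigF factor, which was not tested, because such a batch would hold only these 2 genotypes.

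The sigF2 value was not lower in the libraries labelled SigF2. Reads from the end of the locus beyond an insertion are a candidate explanation: the ratio of the predicted RNA 3' of sigF2 to sigF2 was above all 24 other libraries in 7 of 8 libraries labelled SigF2, and the insertion site is not given in the sources used here. D4 libraries of another of the 3 genotypes are argued against, as the lowest D4 ratio was 0.237 and the other 24 libraries had 0.107 to 0.171. At D1 the ratio of replicate 4, 0.164, lay inside that range and decides nothing. D1 libraries of another genotype are argued against by other genes, 20 per genotype picked at D4 alone: all 4 D1 libraries labelled SigF2 lay nearer to SigF2_D4 than every D1 library of WT, PilB and SigF1, by more than the SD of those groups. On a scale from the other genotype at D4 (0) to SigF2_D4 (1), replicate 4 had 1.02, 1.07 and 1.06 for WT, PilB and SigF1. The highest D1 libraries of WT, PilB and SigF1 had -0.08, 0.72 and 0.70. On the WT scale replicates 1, 2 and 3 had 0.51, 0.45 and 0.94, and on the other 2 scales 1.03 to 1.08. D1 libraries of PilB (0.67 to 0.72) and SigF1 (0.52 to 0.70) already lay toward SigF2_D4, so those 2 scales part the genotypes less at D1. No biological explanation was tested.

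The D1 libraries numbered 4 lay toward D4 along the D1 to D4 axis, at 0.54 of the way in WT, 0.29 in PilB, 0.17 in SigF1 and 0.52 in SigF2. Exchanged D1 and D4 labels within a genotype are argued against, since no D4 library lay below 0.65 and the other D1 libraries reached at most 0.1. A different total share of stable RNA is argued against as well, since that share lay within the range of the other D1 libraries in 3 of 4 genotypes. That total includes rRNA. With rRNA set aside, the stable RNA share of the D1 library numbered 4 was the highest of its group in all 4 genotypes. The part of these other stable RNAs was not tested and stays open. The predicted RNA share of the D1 libraries numbered 4 was the highest of their group in all 4 genotypes (2.47% in WT, 2.84% in PilB, 7.77% in SigF1 and 7.52% in SigF2). Its part in the position was not tested. A later culture stage might explain the position, but it stays open: the lowest position was 0.17, not beyond the others by more than their range, and the labels give no sampling times.

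Other splits of the same libraries tested whether libraries grouped at random would call as many genes. For PilB_D1 against WT_D1, 2 of 35 splits did (115 genes in the real split, 280 in the highest other, libraries 1 and 2 of both strains against 3 and 4), so chance is not excluded; among the 8 splits that part every pair the highest other called 0, and 8 are too few for a share under 0.05. For PilB_D1 against SigF1_D1, 2 of 35 did (543, highest other 561), and chance is not excluded there either. Only the real split, 1 of 35, was as large for SigF1_D1 (564, highest other 387) and SigF2_D1 (608, 186) against WT. The same held for SigF1_D4 (1541, 422) and SigF2_D4 (537, 5) against WT and for PilB against SigF1 at D4 (380, 21). It held for D4 against D1 in PilB (1574, 1048), SigF1 (1685, 528) and SigF2 (669, 388). Same-numbered libraries there had mean correlations of 0.28, 0.28 and 0.3, near the 0.36 of WT. A share of 1 in 35 is the lowest this test can give and was not adjusted over the comparisons. It argues against chance in each comparison alone but does not exclude it. Where same-numbered libraries pair, 1 of 35 splits was as large too: PilB_D4 against WT_D4 (1085, 174), WT_D4 against WT_D1 (750, 739), and SigF1 against SigF2 at D1 (310, 25) and D4 (1298, 358). For these the splits that part every pair are the fair comparison, with highest others of 0, 5, 21 and 0, and 8 such splits are too few for a share under 0.05. In all 4 comparisons of D4 with D1 the highest other split exchanged D1 replicate 4 with D4 replicate 1. Among 100 splits, 2 were as large for the PilB interaction (288, 381) and 1 for the SigF1 interaction (805, 787). For the genes shared by PilB and SigF1, 1 was as large at D1 (64, 58) and 2 at D4 (966, 1021). At both time codes the highest other split keeps the WT libraries together and mixes only PilB and SigF1 libraries. So 58 and 1021 do not show what mixing WT with the mutants gives. All these draws did not keep same-numbered libraries paired, so they do not by themselves exclude chance. For the SigF2 interaction all 100 were as large, at 0 genes against a highest of 22.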

How the results depend on the processing

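The read-count tests with edgeR and DESeq2 that were planned were not run, because the deposited values are normalized and their steps were not taken as reads. Whole numbers of steps could have been formed, since every value was a multiple of the step of its library. Values in this paragraph are genes called unless stated. With the same total the count was 1495 for PilB_D4 against SigF1_D4, 445 for the PilB interaction and 1410 for the SigF1 interaction. A replicate block over all 32 libraries gave 191 for PilB_D1 against WT_D1, 450 for the PilB interaction and 98 shared by PilB and SigF1 at D1. With only the groups compared the counts were 50 for PilB_D1 and 354 for SigF2_D1 against WT_D1, 411 for SigF2_D4 against SigF2_D1, and 240 at D1 and 199 at D4 for PilB against SigF1. With the block as well they were 607 for PilB_D1 against WT_D1, 391 for SigF2_D4 against SigF2_D1, 540 for SigF1_D1 against SigF2_D1, 287 and 230 for PilB against SigF1 at D1 and D4, 451 for the PilB interaction and 122 shared at D1. Without the D1 libraries numbered 4, SigF1_D1 against SigF2_D1 gave 193. With the WT libraries divided between the comparisons, the genes shared at D1 were 39, 38, 35, 32, 35 and 37, and at D4 610 and 617 in the lowest divisions. Of the lists, 1 mutant against WT call was made with an estimated correlation and 48 with fry, against 25. Signs turned with the same total (log2): for Synpcc7942_1510 to -0.68 in SigF1_D4 against WT_D4 and -0.62 against SigF2_D4, for Synpcc7942_1127 to -0.72 in SigF1_D4 against WT_D4, -0.33 in PilB and -0.80 in SigF1 from D1 to D4, -0.53 in SigF1_D4 against SigF2_D4, 0.39 in PilB_D4 against SigF1_D4 and -0.61 in the SigF1 interaction, and for Synpcc7942_1131 to -0.07 in SigF1_D4 against WT_D4 and -0.65 in SigF1 from D1 to D4. With each library left out in turn the ranges against WT were 74 (without PilB_D1 replicate 2) to 154 for PilB_D1, 392 to 625 for SigF1_D1, 385 (without SigF2_D1 replicate 4) to 680 for SigF2_D1, 959 to 1088 for PilB_D4, 1410 to 1499 for SigF1_D4 and 369 to 513 for SigF2_D4. From D1 to D4 they were 507 to 925 in WT, 1406 to 1645 in PilB, 1514 to 1660 in SigF1 and 443 (without SigF2_D1 replicate 2) to 796 in SigF2. SigF1 against SigF2 gave 202 (without SigF2_D1 replicate 3, and also without SigF2_D1 replicate 4) to 347 at D1 and 1110 to 1249 at D4. PilB against SigF1 gave 339 (without PilB_D1 replicate 2; 352 without PilB_D1 replicate 1) to 613 at D1 and 212 (without PilB_D4 replicate 2) to 363 at D4. The interactions gave 175 (without WT_D4 replicate 4; 180 without PilB_D1 replicate 2) to 425 for PilB, 685 to 822 for SigF1 and 0 in every case for SigF2. Shared genes were 47 to 71 at D1 and 855 to 963 at D4. Of 5527 values of named genes under other settings 5307 stayed the same, 147 weakened, 63 strengthened and 10 reversed, all 10 with the same total. Of 4600 with a library left out 4417 stayed, 159 weakened, 24 strengthened and 0 reversed. Many named genes were picked from the same fit for large called changes, and an uncalled gene that stayed uncalled counted as the same. These shares therefore do not measure how stable calls are in general.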

Other observations

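The comparison of the genes beside pilB and the tests with the replicate block on only the groups compared were chosen only after the result was seen.

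Lists of ribosomal protein, ATP synthase, cytochrome b6f and electron carrier, and fatty acid and lipid genes were called lower at D4 than at D1 in all 4 genotypes. Each of these calls was lost with an estimated correlation. Ribosomal protein genes fell from D1 to D4 in PilB (40 of 53, 40 adjusted over the list alone; camera adjusted p = 1.1e-07, and adjusted p = 0.48 with an estimated correlation), in the libraries labelled SigF1 (35 lower and 2 higher, the same adjusted over the list alone; adjusted p = 0.002, and adjusted p = 0.73 with an estimated correlation) and in those labelled SigF2 (36, and 39 adjusted over the list alone; adjusted p = 2.3e-16, and adjusted p = 0.49 with an estimated correlation). Of the 9 ATP synthase genes 9 fell in PilB (adjusted p = 0.0021, and adjusted p = 0.56 with an estimated correlation), 8 in SigF1 (adjusted p = 0.016, and adjusted p = 0.73 with an estimated correlation), 2 in WT (adjusted p = 0.021, and adjusted p = 0.64 with an estimated correlation) and 1 in SigF2 (adjusted p = 0.047, and adjusted p = 0.76 with an estimated correlation). The WT call was lost without WT_D1 replicate 2 or WT_D4 replicate 3 (0.07 to 0.088), and the SigF2 call without SigF2_D1 replicate 1 or 3 or SigF2_D4 replicate 2 or 4 (0.054 to 0.16). With the same total the SigF1 and SigF2 calls of this list were lost, and with quantile normalization the WT and SigF2 calls. The SigF2 call was lost with a mean value of at least 50 as the filter too. Of 11 cytochrome b6f and electron carrier genes 5 fell in WT and 6 in SigF2 (list adjusted p = 0.0025 and 0.0011, and adjusted p = 0.42 and 0.38 with an estimated correlation), and 10 fell in PilB and 10 in SigF1, including cytochrome c6 (Synpcc7942_1630), from 1980 ± 282 to 325 ± 43.1 (SD, n = 4) in SigF1 (list adjusted p = 0.0021 and 0.0023, and adjusted p = 0.48 and 0.53 with an estimated correlation). Of 12 fatty acid and lipid genes 5 fell in WT, 7 in SigF2, 8 in PilB and 9 in SigF1, with 1 higher in SigF1 (adjusted p = 0.0015, 0.0011, 0.0044 and 0.0047, and adjusted p = 0.42, 0.72, 0.48 and 0.66 with an estimated correlation). Synpcc7942_1681, annotated as a thiosulfate-binding protein, fell from 1210 ± 726 to 104 ± 13.4 in PilB, and Synpcc7942_1682, a sulfate permease, fell 7.54-fold. No list of sulfur genes was tested.

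Of the 33 lists tested, 11 were called by camera with the preset correlation at least once among the 6 comparisons of a mutant with WT, with 25 calls. Of these, 1 held with an estimated correlation, that of the pilus list in PilB_D1, which holds pilB itself, and fry gave 48 calls. The other 22 were not called by that camera test on all 32 libraries, which does not show that they did not change. With the replicate block the lists of ATP synthase (0.0039) and 2-component and cyclic nucleotide genes (0.031) were called in PilB_D4. Without the block, the lowest adjusted p of the 22 was 0.051 for high light inducible, cytochrome b6f and carbon fixation genes, 0.067 for secretion, 0.13 for transposon and iron genes and 0.14 for 2-component genes. It was 0.19 for ATP synthase and cell division, 0.21 for inorganic carbon uptake, 0.22 for fatty acid and lipid genes, 0.24 for clock, NDH-1 and competence genes and 0.28 for chaperones and DNA replication. It was 0.36 for oxidative stress, 0.46 for glycolysis, 0.54 for sigma factors, 0.55 for glycogen, 0.57 for chemotaxis and 0.76 for chlorophyll synthesis.

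Genes on the 3' side of pilB were lower in PilB than in the libraries labelled SigF1, with log2 changes of -3.96 for pilT, -3.33 for pilC and -2.26 for Synpcc7942_2068 at D1 and -3.84, -2.85 and -1.85 at D4. On the 5' side grpE (Synpcc7942_2072) had -0.18 (adjusted p = 0.21) and 0.00 (adjusted p = 0.99), which does not show that it was equal. The place of the insertion within pilB is not given in the sources used here, and no explanation was tested.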
